A study of Geobacter sulfurreducens PCA with 6 samples.

How the data were processed

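Total RNA had been extracted with TRIzol and made into libraries with a stranded total RNA kit, per the labels' protocols. The deposited table held 1 column of estimated counts and 1 of length-scaled transcript abundance (TPM) for each of the 6 cultures, with group mean TPM values and the authors' own log2 fold changes, p-values and q-values, per the file headers. Bowtie2, RSEM and DESeq2 are named in the submitters' processing notes; their versions, the genome build and the annotation were not given in the sources used here. The deposited estimated counts were not normalized: they summed to different totals, from 7875093 to 11198449, and 1.76 to 2.09% of values per library were not whole, as when a read is divided between similar features. At least 1 such value was found for 101 features. The TPM values the authors deposited are scaled for feature length and to a fixed total in each library, so a transcript that takes a large share lowers all others. The authors' log2 fold changes and q-values were used for a comparison of calls only. A q-value under 0.05 was given to 2421 features in the authors' deposited table, 1184 higher and 1237 lower; 2389 of them were also called here, with 0 in the opposite direction.

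Sample groups came from the sample titles. The 6 columns were matched to samples by name, and 0 columns of other samples were used. Gene symbols, products, older tags and gene order were taken from the reference table of assembly ASM798v2, in which 3369 of 3391 locus tags were found. The small RNA annotations have no names or positions in the tables used here. The table contained 0 ribosomal RNA and 0 transfer RNA genes, so carry-over of these could not be examined.

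Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Features were filtered with filterByExpr, which removed 171 and left 3464, libraries were scaled with TMM, and the quasi-likelihood test was run with group as the single factor over all 6 libraries. The p-values were adjusted by the Benjamini-Hochberg method at 0.05. The TMM factors were 1.09, 1.062 and 1.181 for the wild type libraries and 0.885, 0.937 and 0.882 for those of T9-1. CPM values in the text are after this scaling, and the biological coefficient of variation was 0.135. Standard errors belong to the log2 fold change of each gene. They were derived from the test, as the size of that change divided by the square root of its F statistic. The smallest p an exact permutation test could give for 3 against 3 is 0.1, so no such test was used for single genes.

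Before the data were examined, 39 gene lists were fixed as expressions matched to product names or symbols. Lists with at least 5 tested genes, 37 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. They were tested again with the correlation estimated from the data. That second setting also takes its degrees of freedom from the 6 libraries, so fewer lists can pass whatever the correlation. The list meant for ribosomal and transfer RNA matched rimM alone. Some members matched by spelling alone, 33 in all, and lists without them were tested as an alternative chosen after seeing the data. Named genes followed a rule fixed beforehand. Its first part took the 8 largest rises and 8 largest falls among called features with a mean of at least 10 CPM and no overlap between groups. The second took carbon-route and electron-transfer genes whatever their result, and the third up to 4 called members with the largest change per described list. At most a pair of small RNA identifiers per direction is printed, since they have no names.

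The functions were tested on simulated data with 200 of 3464 genes changed by known amounts. For the comparison of T9-1 with wild type they recovered 56% of 1.5-fold, 84% of 2-fold and 100% of 4-fold and 8-fold changes, and 17 of 186 calls (9.1%) were false, above the nominal 5%. This was a single simulated draw with far fewer changed genes than the 2458 called in the data. Its shares of recovered and false calls therefore do not carry over directly. Replicate libraries were compared for identity: the chi-square per degree of freedom between replicates was 30.52 to 58.59, far above sampling noise, so each counted as a separate sample.

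Alternatives were median-of-ratios and upper-quartile scaling, library totals alone, DESeq2 1.42.0, limma-voom, other filters, a block for replicate number, a test against a 1.5-fold change, log2(TPM + 1) in limma-trend, and leaving out each library in turn. Added after seeing the data were an adjusted p under 0.001, leaving out dcuB, and leaving out the small RNA annotations. Gene order tests used Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.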

Results

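RNA was sequenced from 6 cultures of Geobacter sulfurreducens PCA, an anaerobic bacterium that oxidises acetate and passes the electrons to fumarate, metals or electrodes. The 3 wild type cultures grew on 10 mM acetate as electron donor with 40 mM fumarate as electron acceptor. The other 3 cultures were of the adapted strain T9-1, which had gone through 9 transfers on fumarate without acetate and grew here on 40 mM fumarate alone. All were harvested in mid-log phase at 30 °C, from separate cultures grown in triplicate. The table held estimated counts for 3635 features, of which 3391 were locus tags and 244 were small RNA annotations. Totals were 11198449, 10472656 and 11062946 counts in the wild type libraries and 7875093, 8697397 and 9513456 counts in the T9-1 libraries. A count of 0 in these libraries allowed a level of up to 0.23 to 0.43 CPM (counts per library total after TMM scaling), for counting error alone. Features are named by symbol or by the older GSU tag in the reference gene table of assembly ASM798v2. The build behind the counts was not given in the sources used here, so no coordinates are printed.

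The comparison of T9-1 on fumarate with wild type on acetate and fumarate asked which transcripts differed between a strain living on fumarate alone and its parent respiring acetate. The most abundant transcript of T9-1 was dcuB (GSU2751), annotated as an anaerobic C4-dicarboxylate transporter, at 197600 ± 22500 CPM (SD, n = 3) against 18590 ± 1280 CPM in the wild type, a 10.6-fold rise. It took 17.08, 16.65 and 19.58% of all counts in the T9-1 libraries and 2.19, 1.88 and 2.13% in the wild type libraries. Malic enzyme, pyruvate:ferredoxin oxidoreductase and fumarate reductase transcripts also rose. Those of pyruvate carboxylase, isocitrate dehydrogenase, malate dehydrogenase, most NADH dehydrogenase genes, a formate dehydrogenase and the extHIJKL electron conduit fell. An arsenate reductase gene and a heavy-metal-associated protein gene, both at low levels in the wild type, were among the largest rises. Of 3464 features tested by edgeR's quasi-likelihood test, 2458 (71%) changed at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1227 were higher and 1231 lower in T9-1, and 1179 differed at least 2-fold, 658 of them higher and 521 lower. The 2 groups did not overlap for 75.1% of the features, where chance gives 10%.

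Among the 21 carbon-route genes chosen before the data were examined, 8 rose, 9 fell and 4 were not called. NADP-dependent malic enzyme, maeB (GSU1700), which forms pyruvate from malate, rose 3.3-fold from 1793 ± 339 to 5909 ± 99.3 CPM (log2 fold change 1.72, SE 0.14, adjusted p = 4.9e-06). Pyruvate:ferredoxin oxidoreductase, por (GSU0097), which interconverts pyruvate and acetyl-CoA, rose 2.02-fold to 11030 ± 317 CPM (adjusted p = 6.2e-05). The 3 subunit genes of the fumarate reductase and succinate dehydrogenase complex rose by smaller amounts, frdC (GSU1176) 1.94-fold, frdA (GSU1177) 1.53-fold and frdB (GSU1178) 1.54-fold. The succinyl-CoA synthetase genes sucC (GSU1058) and sucD (GSU1059) rose 1.85-fold and 1.59-fold. Of these 5, frdA, frdB and sucD were not called on the TPM scale (log2 fold changes 0.22, 0.24 and 0.28, adjusted p = 0.25, 0.23 and 0.14) or against a 1.5-fold change (adjusted p = 0.36, 0.28 and 0.17). Pyruvate carboxylase, pyc (GSU2428), which makes oxaloacetate from pyruvate, fell 12.9-fold from 900.9 ± 78.2 to 70.07 ± 13.7 CPM (log2 fold change −3.69, SE 0.15, adjusted p = 5.6e-08). Pyruvate phosphate dikinase, ppdK (GSU0580), was 4.82-fold lower and the second succinyl-CoA:acetate CoA-transferase gene, ato-2 (GSU0174), 5.79-fold lower. Isocitrate dehydrogenase, icd (GSU1465), fell 3.25-fold, malate dehydrogenase, mdh (GSU1466), 3.02-fold and acetate kinase, ackA (GSU2707), 1.95-fold. The 2-oxoglutarate:ferredoxin oxidoreductase genes korA (GSU1468) and korB (GSU1469) and fumarase, fumB (GSU0994), were lower by 1.34-fold, 1.37-fold and 1.2-fold. In the test against a 1.5-fold change korA, korB and fumB were not called. The log2 fold changes of citrate synthase gltA (GSU1106), ato-1 (GSU0490), pckA (GSU3385) and pta (GSU2706) were 0.11, 0.24, 0.19 and 0.23, and none of these 4 passed the test. Without wild type replicate 2, ato-1, pckA and pta passed (adjusted p = 0.019, 0.0496 and 0.036), and pta also passed with the stricter filter (log2 fold change 0.27, adjusted p = 0.039).

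**Figure D1:**
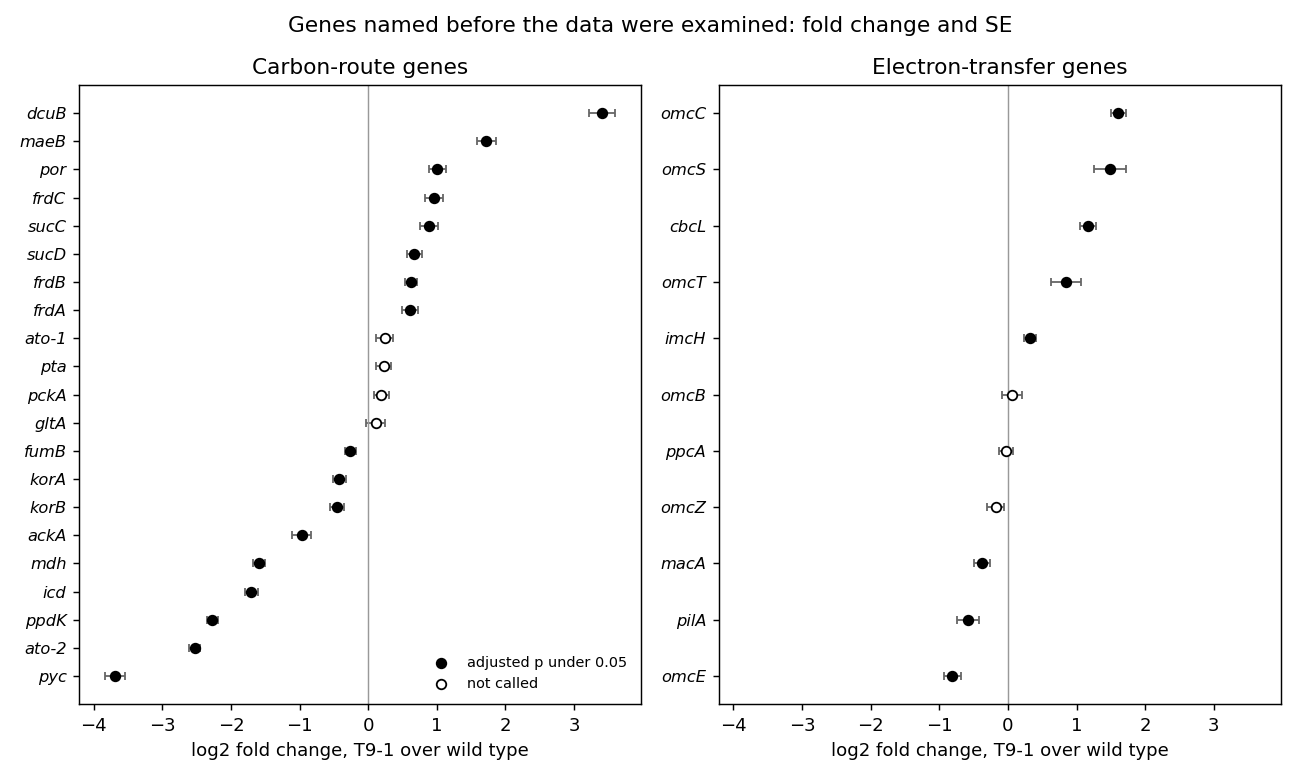
Log2 fold change of T9-1 over wild type (horizontal axis) for the 21 carbon-route genes on the left and the 11 electron-transfer genes on the right. Points are estimates from 3 cultures against 3, bars are 1 standard error derived from the test's F statistic, and open points did not pass an adjusted p of 0.05. The gene dcuB lies at 3.41 and pyc at −3.69.

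In the tricarboxylic acid cycle list, 5 of 15 tested genes rose and 8 fell, and the list as a whole did not pass camera's test (adjusted p = 0.23). Besides icd and mdh, its largest falls were in aconitase acnB (GSU1660), 3.31-fold, and the 2-oxoglutarate dehydrogenase component odhB (GSU2448), 3.3-fold. In the list around pyruvate, phosphoenolpyruvate and acetyl-CoA, 5 of 20 rose and 9 fell (adjusted p = 0.56), and 6 of its members had entered by spelling alone. Without them 2 of 14 rose and 7 fell, at a median of −0.24 (adjusted p = 0.21). All 5 genes of the dicarboxylate and acetate transport list were called, 3 higher and 2 lower. The list missed the threshold (adjusted p = 0.067), and leaving out wild type replicate 2, T9-1 replicate 2 or T9-1 replicate 3 brought it to 0.048, 0.036 and 0.03. It rose to 0.24 and 0.18 without wild type replicates 1 and 3 and to 0.57 by camera on ranks, with an adjusted p = 0.80 with an estimated correlation. Its acetate symporters diverged: GSU1068 rose 13.2-fold from 49.77 ± 7.57 to 655 ± 22.6 CPM and GSU2352 rose 2.48-fold, while GSU1070 fell 4.24-fold from 2217 ± 588 CPM.

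NADH dehydrogenase transcripts were lower as a group: 22 of 25 tested genes fell, 1 rose and 2 were not called, with a median log2 fold change of −0.98 (camera adjusted p = 7.0e-04 with a preset correlation, and adjusted p = 0.80 with an estimated correlation). Adjusted over the list alone, 23 fell and 1 rose. Counting only genes with NADH in the product name, all 12 tested at GSU0338 to GSU0351 fell, as did 10 of 11 at GSU3429 to GSU3445. Their medians were −0.97 and −1.08, and other genes of these clusters were not counted. Subunit A (GSU3445) fell 4.18-fold and nuoE (GSU3443) 3.43-fold. The member that rose, GSU0740, lies in a gene cluster with hydrogenase subunits and was 5.73-fold higher. Of 10 ATP synthase genes 4 rose, led by GSU0335 and GSU0334 at log2 fold changes of 0.86 and 0.77, and 6 were not called (adjusted p = 0.76). On the TPM scale 2 ATP synthase genes were lower and 0 higher, and GSU0335 and GSU0334 were not called (adjusted p = 0.073 and 0.057). In the test against a 1.5-fold change GSU0335 was not called (adjusted p = 0.076).

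Hydrogenase genes went both ways, 14 higher and 10 lower of 29 tested (adjusted p = 0.81). GSU0739 and GSU0734, both annotated as hydrogenase, rose 16.7-fold and 10.4-fold. In the cluster GSU0777 to GSU0788, which holds an uptake hydrogenase and a formate dehydrogenase, 11 of 12 tested genes fell, with a median log2 fold change of −3.26. Its formate dehydrogenase catalytic gene fdnG (GSU0777) fell 16.3-fold from 635.2 ± 164 to 38.91 ± 3.11 CPM. Both genes of the formate dehydrogenase list, fdnG and fdhD (GSU0780), fell, and 2 genes were too few for a list test. The 4Fe-4S protein GSU0778 fell 53.4-fold, and the cytochrome b subunit GSU0779 27.6-fold.

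Of 11 electron-transfer genes chosen before the data were examined, 5 rose, 3 fell and 3 were not called. The multihaem outer membrane cytochrome genes omcC (GSU2731) and omcS (GSU2504) rose 3.06-fold and 2.81-fold, and omcT (GSU2503) 1.81-fold. The rises of omcS and omcT were from low levels, 17.68 ± 5.39 and 10.06 ± 1.12 CPM in the wild type, against 4164 ± 224 CPM for omcC. The inner membrane cytochrome genes cbcL (GSU0274) and imcH (GSU3259) rose 2.25-fold and 1.25-fold. Counts of omcC and its near copy omcB (GSU2737) were not whole numbers in at least 1 library, so reads were divided between features and their separate levels are uncertain. The pilin gene pilA (GSU1496) fell 1.49-fold from a low level of 18.8 ± 1.27 CPM, omcE (GSU0618) 1.76-fold and macA (GSU0466) 1.3-fold. The log2 fold changes of omcB, omcZ (GSU2076) and ppcA (GSU0612), 0.06, −0.18 and −0.03, did not pass, though omcZ did without wild type replicate 3 (log2 fold change −0.29, adjusted p = 0.016). Both omcZ and ppcA were called lower with library totals as the only scaling (log2 fold changes −0.47 and −0.33, adjusted p = 0.0015 and 0.012) and on the TPM scale (−0.56 and −0.41, adjusted p = 0.0073 and 0.034). Without wild type replicate 1 or 2 the call of macA ended (adjusted p = 0.057 and 0.052), and without T9-1 replicate 2 or 3 that of imcH did (0.062 and 0.0501). With library totals alone imcH was at a log2 fold change of 0.02 (adjusted p = 0.85). In the test against a 1.5-fold change omcT (adjusted p = 0.097), pilA (adjusted p = 0.47), macA and imcH were not called. On the TPM scale omcT was not called either (log2 fold change 0.36, adjusted p = 0.1). In the c-type cytochrome list, whose product-name match left out omcB, omcC and omcZ, 17 of 66 rose and 27 fell (adjusted p = 0.34). With library totals alone 12 rose and 38 fell, and on the TPM scale 10 of 64 rose and 37 fell. The furthest down in the list was extKL (GSU2937), 45.9-fold, and the furthest up was GSU0701, at 11 counts over the wild type libraries and 132 over the T9-1 libraries. Of 37 genes in the type IV pilus and pseudopilin list 5 rose and 16 fell, 15 adjusted over the list alone (adjusted p = 0.33). Without 7 members that had entered by spelling alone, 2 of 30 rose and 14 fell. The full pilus list had 4 rises and 24 falls with library totals alone and 4 and 26 on the TPM scale. GSU2036 and the minor pilin gene GSU2034 fell 4.73-fold and 4.14-fold.

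**Figure D2:**
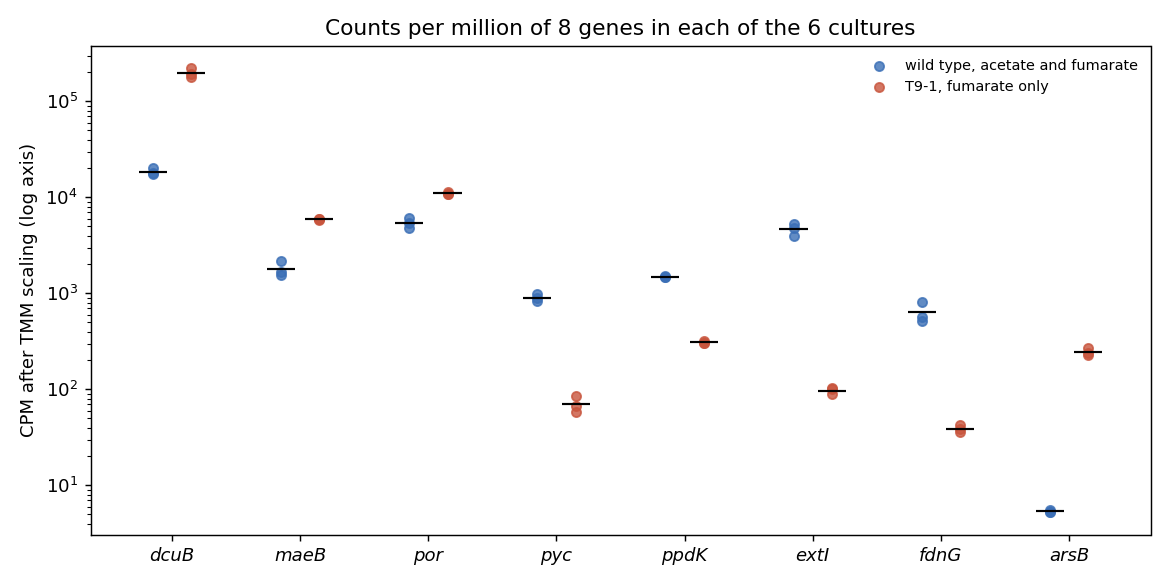
CPM after TMM scaling (vertical axis, log scale) of 8 genes in each of the 6 cultures. Points are single cultures, blue for wild type on acetate and fumarate and red for T9-1 on fumarate, and bars are group means; the groups are separated for each of the 8 genes, and arsB rises from between 5.215 and 5.588 to between 228 and 271 CPM.

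By the rule fixed beforehand, the 8 largest rises and falls among called features with a mean of at least 10 CPM and no overlap were listed. A rise could reach that mean through T9-1 alone. The folds of several rises thus rest on few wild type counts, such as 11, 8 and 11 for GSU2953. The falls included the whole extHIJKL operon, which encodes an outer membrane electron conduit: extJ (GSU2938) was 51.4-fold lower, extI (GSU2939) 48.1-fold, extKL 45.9-fold and extH (GSU2940) 41.1-fold. The gene extI went from 4667 ± 634 to 97.01 ± 7.43 CPM (log2 fold change −5.59, SE 0.15, adjusted p = 8.1e-09). GSU0967, a hypothetical protein, fell 34.7-fold from 2610 ± 376 CPM, and GSU0778 and GSU0779, described with the formate dehydrogenase, completed the protein-coding falls. The small RNA annotation sRNA0208 fell from 97.93 ± 56.7 to 0.891 ± 0.0541 CPM. Among the rises, the group II intron reverse transcriptase gene GSU2471 went from 1.38 ± 0.424 to 234.8 ± 34.8 CPM, and its neighbour GSU2472, a VapC family toxin, rose 69-fold to 1279 ± 60.1 CPM. The arsenate reductase gene GSU2953 rose 106-fold to 88.42 ± 8.21 CPM, and GSU1338, with a heavy-metal-associated domain, 52.4-fold to 100.7 ± 7.29 CPM. The TetR family regulator gene GSU2741 was uneven in the wild type, with 3, 19 and 0 counts, against 257, 231 and 490 counts in T9-1. The small RNA annotations sRNA0149 and sRNA0150 had 4 and 6 counts over the wild type libraries and 685 and 962 over the T9-1 libraries. Their ratios of shares were 215 (95% exact interval 83.5 to 791, counting error only) and 201 (92.1 to 550). A further small RNA annotation was 113-fold higher in the fit, with 7, 0 and 1 wild type counts. Of 158 small RNA annotations tested 55 rose and 79 fell, and they took 1.51 to 1.91% of wild type and 2.46 to 2.74% of T9-1 counts.

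Oxidative stress genes fell as a group, 16 of 21 with 3 higher, at a median log2 fold change of −1.1 (camera adjusted p = 6.7e-05 with a preset correlation, and adjusted p = 0.80 with an estimated correlation). The counts adjusted over the list alone were the same. The glutaredoxin family gene GSU2812 fell 13.2-fold, the neighbouring cytochrome c peroxidase gene GSU2813 9.58-fold from 3487 ± 225 CPM, and the rubrerythrin gene rbr (GSU2814) 6-fold. Several members, such as the rubredoxin GSU0847, which fell 5.28-fold, are small redox proteins that also serve in other electron transfers. Genes of polysaccharide and envelope glycan synthesis were higher as a group, 31 of 62 with 5 lower, at a median of 0.43 (camera adjusted p = 0.014 with a preset correlation, and adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone, 31 rose and 4 fell. With library totals as the only scaling 22 rose and 10 fell, at a median of 0.13, and on the TPM scale 18 rose and 10 fell, at a median of 0.04. The exopolysaccharide glycosylphosphotransferase gene GSU1846 rose 19.1-fold from 3.302 ± 0.595 CPM, and the glycosyltransferase genes GSU3542 and GSU1957 rose 6.64-fold and 6.63-fold.

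**Figure D3:**
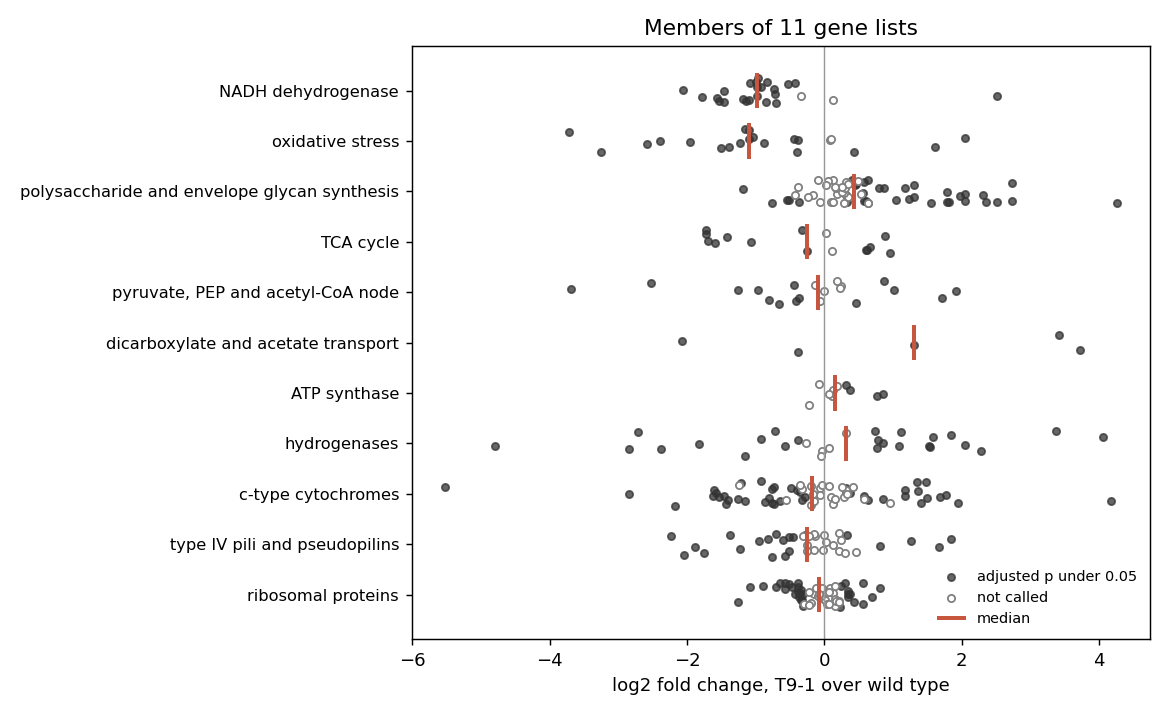
Log2 fold change of T9-1 over wild type (horizontal axis) for the tested members of 11 gene lists fixed before the data were examined. Each point is a gene, filled where its adjusted p was under 0.05, and the red bar is the list's median, which was −0.98 for NADH dehydrogenase, −1.1 for oxidative stress and 0.43 for polysaccharide synthesis.

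In the CRISPR and toxin-antitoxin list 11 of 27 rose and 2 fell, 10 and 0 adjusted over the list alone. The list missed the threshold (adjusted p = 0.067), and it passed at 0.029 with library totals as the only scaling and at 0.038 with a replicate block. It also passed at 0.048, 0.044 and 0.043 without wild type replicate 2, T9-1 replicate 2 and T9-1 replicate 3. Its adjusted p was 0.80 with an estimated correlation, 0.18 by camera on ranks and 0.088 without wild type replicate 1. The antitoxin gene GSU0737 and the PemK/MazF family toxin gene GSU0736 rose 21-fold and 18.7-fold. Both lie in a stretch of 6 adjacent risen genes, GSU0734 to GSU0740. That stretch also holds the hydrogenase genes GSU0734 and GSU0739 and the NADH dehydrogenase list member GSU0740, so these rises share 1 locus. Among chaperones and proteases 12 of 27 rose and 9 fell, and 5 members had entered by spelling alone, without which 10 of 22 rose and 7 fell. The adjusted p was 0.34, with 0.0497 without wild type replicate 2, 0.57 by camera on ranks and adjusted p = 0.93 with an estimated correlation. The small heat shock protein gene GSU2408 rose 24-fold from 216.4 ± 37.9 to 5184 ± 192 CPM. Of 40 genes in the DNA repair and SOS list, 9 of which had entered by spelling alone, 16 rose and 10 fell (adjusted p = 0.34), and without these members 15 of 31 rose and 9 fell. A lexA repressor gene (GSU0041), a DNA polymerase IV gene (GSU0043) and uvrB (GSU3262) rose 6.06-fold, 6.43-fold and 5.44-fold. The symbols of GSU0041 and GSU0043 are also used by other genes, whose values are not given here. These genes, GSU0041 and GSU0043, lie in the same stretch of 4 adjacent risen genes, GSU0040 to GSU0043. With library totals as the only scaling, and on the TPM scale, more genes fell than rose in both the chaperone and the DNA repair lists.

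In the nitrogen fixation and ammonium assimilation list 4 of 21 rose and 12 fell (adjusted p = 0.34), and the P-II regulator gene GSU1836 fell 9.62-fold from 1739 ± 642 CPM. Among iron and metal ion uptake genes 7 of 17 rose and 8 fell (adjusted p = 0.99). The ferrous iron transport genes GSU3270 and GSU3268 fell 14.5-fold and 9.71-fold. Of 8 phosphate uptake genes 5 rose and 0 fell (adjusted p = 0.41), though from low levels, 1.19 ± 0.244 CPM in the wild type for the phosphate-binding protein gene GSU1099. Among efflux pumps 15 of 37 rose and 7 fell, 14 and 7 adjusted over the list alone (adjusted p = 0.48), led by the arsenite transporter gene arsB (GSU2954), which rose 45.6-fold. The rises and falls of efflux pumps were 12 and 11 with library totals alone and 8 and 10 on the TPM scale. ABC transporters had 42 rises and 25 falls of 98 (adjusted p = 0.23), against 29 and 31 with library totals alone and 25 and 32 on the TPM scale. Of 56 ribosomal protein genes 12 rose and 20 fell, 19 adjusted over the list alone, with a median of −0.08 (adjusted p = 0.69). With library totals as the only scaling 4 rose and 35 fell, at a median of −0.38, and on the TPM scale 1 rose and 32 fell, at a median of −0.47. The largest falls there, rplU (GSU3236) and rpmA (GSU3235), were 2.39-fold and 2.12-fold. Aminoacyl-tRNA synthetase genes had 6 rises and 7 falls of 22 (adjusted p = 0.81), against 2 and 13 with library totals alone and 0 and 13 on the TPM scale.

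The biosynthetic lists did not pass. Rises and falls were 5 and 6 of 14 for aromatic amino acids, 2 and 0 of 7 for branched-chain amino acids, 9 and 9 of 28 for other amino acids, 7 and 6 of 16 for purines and pyrimidines, 2 and 3 of 8 for fatty acids, and 5 and 4 of 16 for cobalamin and haem. Within them citramalate synthase, cimA (GSU1798), which begins isoleucine synthesis from pyruvate, rose 2.56-fold, while the cysteine synthesis genes cysE (GSU2572) and cysK (GSU0535) fell 4.1-fold and 3.42-fold. Glycolysis and gluconeogenesis had 2 rises and 7 falls of 15, flagella 3 and 9 of 35 (1 and 7 adjusted over the list alone), chemotaxis 19 and 13 of 54, and cytochrome c biogenesis 7 and 5 of 14. The flagella counts were 1 and 17 with library totals alone and 1 and 20 on the TPM scale. Type II secretion had 5 and 4 of 14, peptidoglycan and cell division 15 and 11 of 39, and outer membrane proteins and lipoproteins 17 and 28 of 63. Among regulators, two-component systems had 28 and 40 of 87, cyclic nucleotide signalling genes 14 and 16 of 38, and transcription regulators 48 and 36 of 109, which became 37 and 46 with library totals alone and 32 and 46 on the TPM scale. Transposases and phage genes had 13 and 10 of 38. Among these falls, the transposase genes GSU0555 and GSU1355 of the same element had equal counts in every library, as when reads are divided evenly between copies. They were counted as separate falls. Adjusted over the list alone, rises and falls were 8 and 9 for other amino acids, 4 and 4 for cobalamin and haem, 15 and 10 for peptidoglycan, 30 and 41 for two-component systems and 49 and 36 for transcription regulators. Where no such count is given for a list, it equalled the count over all genes tested. In 6 of the 37 lists tested, all uncalled, the median, the mean and the direction of the test differed in sign.

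Of the 37 lists 3 passed camera's test with a preset correlation of 0.01, and 0 did with an estimated correlation, where 1 list had an unadjusted p under 0.05. The estimated correlation of the polysaccharide list was −0.007, under the preset value, so correlation between its genes does not account for its lost call. Strain and medium changed together, so neither can be assigned a change on its own. Scaling by library totals alone moved the median log2 fold change by −0.3 and the split of calls to 871 higher and 1616 lower, and in 12 lists the larger of the counts of rises and falls switched side. The TPM alternative, which changed the test and the filter along with the scale, moved the median by −0.37 and the split to 717 higher and 1633 lower. With it 14 lists switched side. Rises were fewer than with TMM in 33 and 35 of the 37 lists and falls more in 34 and 33, with library totals and TPM in that order, and in 0 lists did either count move the other way. The lists that switched side on both scales were cytochrome c biogenesis, type II secretion, chemotaxis, purines and pyrimidines, chaperones, transcription regulators, transposases and phage, peptidoglycan, DNA repair, cobalamin and haem, and ABC transporters. Branched-chain amino acids switched with library totals only, and ATP synthase, hydrogenases and efflux pumps on the TPM scale only. On the TPM scale frdA, frdB, sucD, omcT, GSU0335 and GSU0334 lost their calls, and imcH changed sign to −0.07 without a call.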

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

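The threshold of 0.001, leaving out dcuB or the small RNA annotations, and lists without members matched by spelling were chosen after seeing the data. Of 2162 values of 121 named genes under the alternatives, 2130 kept direction and side of the threshold, 22 lost the call, 9 gained one and 1 was reversed: imcH, −0.07 in limma-trend on TPM. The log2 fold change of imcH was 0.32 in the main fit, and the median of all genes moved by −0.37 on TPM. A shift of that size is enough to change its sign, and no other cause was tested. The 2458 changed genes became 1447 (757 higher, 690 lower) in the test against a 1.5-fold change and 1526 (765 higher, 761 lower) at an adjusted p under 0.001, both stricter by construction. The count of higher genes became 717 on TPM, where the median of all genes moved by −0.37. Leaving out each library gave 2264 to 2508 changed genes, 1105 to 1258 higher, 1159 to 1250 lower and 1163 to 1218 changed at least 2-fold. In every alternative compared, 0 genes called in both had the opposite direction. The 3 called lists became 0 with an estimated correlation, and 3 to 6 when each library was left out: 6 without wild type replicate 2, 5 without T9-1 replicate 2 and 5 without T9-1 replicate 3. Correlations of deviations from the group mean between cultures of the same replicate number were 0.09, 0.07 and −0.07. These gave no sign of pairing, but with 3 cultures per group they cannot exclude it. A replicate block called 2410 genes, with the CRISPR and toxin-antitoxin list at an adjusted p of 0.038. Leaving out ribosomal and transfer RNA could not be run, because the table has none, and the choices for data with normalized values alone did not apply. Thinning every library to the smallest total gave 2423 changed genes. In the simulation, which had far fewer changed genes than the data, 56% of 1.5-fold changes were recovered, and this was not split by expression level.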

Other observations

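The themes and genes of this part and its tests were chosen after the results were seen, except the tests of shuffled gene order and of distance from the replication origin. A scan of 146 product words, each on at least 8 tested genes, called 7 with camera's preset correlation and 0 with an estimated correlation. Genes with PEP-CTERM in the product name led it: 7 of 9 tested genes rose and 1 fell, with a median log2 fold change of 2.05 (adjusted p = 4.6e-06 with a preset correlation, and adjusted p = 1.0 with an estimated correlation). PEP-CTERM is a sorting signal often found beside exopolysaccharide genes. The 9 include parts of its system, such as prsT and prsK, besides proteins named for the sorting domain. The sorting-domain gene GSU1079 rose 23.7-fold from 188.7 ± 23.2 to 4471 ± 772 CPM (SD, n = 3), prsT (GSU1987) 6.05-fold and GSU1994 5.87-fold. The histidine kinase gene prsK (GSU1941), the member that fell, was 1.77-fold lower. The regulator gene prsR (GSU1940), whose product name writes the word in a longer hyphenated form and so was not counted among the 9, fell 2.32-fold. The hypothetical protein genes GSU3409 and GSU3410 came next to dcuB in abundance in T9-1, at 69890 ± 12600 and 61710 ± 14400 CPM, after rises of 4.26-fold and 2.25-fold. The OFA family transporter gene GSU2490 fell 26.2-fold from 1150 ± 113 CPM, and glutamine synthetase glnA (GSU1835) fell 4.05-fold from 6214 ± 1620 CPM.

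Other neighbouring genes moved together. All 6 tested genes of the branched-chain amino acid transporter cluster GSU2005 to GSU2010 rose, with a median of 3.37, as did 6 of 6 heterodisulfide reductase-like genes at GSU0087 to GSU0092, with a median of 1.99. All 4 genes of the arsenic cluster GSU2952 to GSU2955 rose, between 4.01 and 6.72. The molybdenum cofactor genes and adjacent ABC transporter genes at GSU2699 to GSU2704 fell in 6 of 6 cases, with a median of −1.86, and the 5 genes GSU1235 to GSU1239 fell with a median of −3.31.

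The first pattern weighed was the rise of dcuB. The tables argue against reads shared with another gene, since 0 of 6 libraries had a dcuB count that was not whole, and against scaling, since its lowest log2 fold change over the alternatives was 3.02. Extra copies of a region reaching to both sides of dcuB, as the sole source of its rise, are argued against by its neighbours. The 5 tested genes after dcuB had a median of −0.55 and the 5 before it 1.05, against 3.41 for dcuB. All 5 genes before it were called higher, between 0.68 and 2.25, so a region with fewer copies that ends near dcuB is not excluded. Extra copies of dcuB alone or with the genes before it, a change in its promoter, and regulation by the medium stay open, since strain and medium changed together.

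The second pattern was that large changes lay in runs along the chromosome. There were 27 runs of 3 or more adjacent tested genes changed at least 4-fold in the same direction, 18 higher and 9 lower, while 1000 shuffled gene orders gave at most 4. Loss of segments from T9-1 is argued against by 0 genes of the fallen runs having 3 or fewer counts in every T9-1 library, and segments missing from the wild type by 0 genes of the risen runs at that floor in every wild type library. Shuffling also breaks up operons, so the comparison shows only that large changes were not placed at random along the chromosome. Operons that switch together may account for the runs, which was not tested against an operon map.

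The third pattern was the breadth of change. Deeper wild type libraries are argued against as its cause, since 2423 genes were called after thinning every library to the smallest total. A gene dosage gradient is argued against by a rank correlation across genes of 0.016 between fold change and distance from the origin in gene order. Only 10 splits of the 6 libraries exist, too few for a share under 0.05: the real split called 2458 genes, 1 of 10 splits reached that count, and the highest other split called 0. For gene lists with a preset correlation the real split called 3 and the highest other split 7, with 8 of 10 splits calling at least as many. Every other split has cultures of both groups on each side, in unequal numbers. It thus keeps part of the real contrast and widens the spread within each side. The splits therefore cannot show whether the count of genes or of lists stands out. Strain, medium and growth rate stay open and untested.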
